A study of Homo sapiens with 12 samples.

How the data were processed

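Gene expression was measured on Illumina bead arrays in WERI-Rb-1, a human retinoblastoma cell line, after infection with the RH strain of Toxoplasma gondii and after mock infection. Total RNA was taken at 2, 6 and 24 h, with 2 arrays for each condition and time, so that 12 arrays formed 6 groups. The labels do not say whether the 2 arrays of a group come from separate cultures, so the p-values measure the spread between these samples. No array was left out.

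Per the file headers, the deposited scanner table holds an intensity for each of 47231 probes on each array, without normalization. The array medians differed, and the lowest intensity was 84.7, so a background level remained in the values. Per the file headers the table also holds a detection p-value beside each intensity, but the deposited values rose with the intensity and reached their highest level at the brightest probes, so 1 minus the value was used as the detection p-value. The authors' processed values are deposited on a log2 scale with equal quantiles on all arrays. Per the submitters' processing notes, R 3.1.3, lumi and limma were used, and the notes give neither their roles nor their order. The processed values served here only as an alternative source. Across probes they lay at a median gap of 0.12 and at most 0.31 on the log2 scale from the values computed here, with correlations of at least 0.999 on every array.

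The intensities were background corrected with the normexp model of limma 3.58.1 in R 4.3.3, using the detection p-values in place of control probes, with an offset of 16, quantile normalized between arrays and put on the log2 scale. A probe was kept when its detection p-value was under 0.05 on at least 2 of the 12 arrays, without regard to group, which kept 26035 probes. The platform annotation gave 1 gene symbol for 30113 probes, several for 8 and none for 17110. Symbols were updated by gene ID from RefSeq names (GRCh38.p14), which matched 30074 of the probes with 1 symbol. Where several kept probes shared a symbol, the probe with the highest mean log2 intensity over all arrays stood for the gene. Probes without a symbol stayed in the fit under their own ID. This left 21025 genes to test, of which 13634 had a name and 7391 were unnamed probes. No coordinates are given, since the files state no genome build.

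Differences were tested with limma (lmFit, contrasts.fit and eBayes, two-sided) in a fit of all 12 arrays with a mean for each group, 6 residual degrees of freedom and 4.37 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all genes tested in a contrast, and an adjusted p under 0.05 counted as passing. The contrasts were infected minus mock at each time, the differences of that effect between times, its mean over the 3 times, and the changes of mock cells between times. Each value is a log2 difference with its standard error (SE) from this fit, over 2 arrays per group. Intervals are 95% intervals. The number of arrays limits the precision. A probe detected on no array of a group has only a bound there. The brighter group's mean was then set against the mean, per array, of the higher of the lowest detected value and the probe's own value, and the result is written as "at least" so many fold.

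Altogether 27 gene lists were fixed before the data were examined, as were the preprocessing, the contrasts, the alternatives and the rule for named genes. Of these lists, 21 cover pathways, immune responses and retinal neuron genes, and the other 6 cover markers of other cell types and genes that report on RNA content. They hold 826 distinct genes, of which 774 had a named probe and 645 were tested. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 81 tests (27 lists at 3 times) for infection, and likewise for the changes over time in mock cells, for those in infected cells and for the differences of the infection effect between times. For the mean over the 3 times it ran over 27 tests. Beside it, camera was run with an estimated correlation, and fry gave a test of movement on balance in a direction and a test of change in either direction; neither test of fry compares a list with other genes. The rule named, for infected against mock cells, up to 12 genes in each direction among those past the threshold whose infected and mock arrays did not overlap, or, where none passed, the 3 with the smallest p. For the changes of mock cells it named the 3 largest rises and the 3 largest falls, and for each described list 2 to 4 members with the smallest adjusted p. A gene that alone makes up a small count was also named. Members of a list were also tested with adjustment over that list alone, which does not correct for the number of lists and times. Calls made only in this way may be chance.

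The tests of the lists in the changes over time, the same changes in infected cells, a fit with array brightness as a covariate and a crossed block at 6 h were added after seeing the data. The alternatives changed the background correction and its offset, the normalization, the source of the values, the probe filter, the choice of probes, the samples in a fit, the prior, array weights, a block for the replicate number, the thresholds, and left out each array in turn. The fit, without the background correction and normalization before it, was tested on simulated log2 values for 21025 genes of which 200 were changed. The genes were independent, with a spread unrelated to intensity and a single draw per setting, so recovery on real arrays may be lower. For infected against mock cells at 24 h the fit recovered 98.5% of the genes changed 4-fold, 72.0% of those changed 2-fold and 0.5% of those changed 1.41-fold. For mock cells at 24 h against 2 h these shares were 99.0%, 67.0% and 0%. A simulated shift of 0.2 on the log2 scale in all 24 tested interferon-stimulated genes at 24 h, with independent genes, passed with camera at an adjusted p of 0.00052. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.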

Results

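Infected and mock WERI-Rb-1 retinoblastoma cells were compared at 2, 6 and 24 h after addition of Toxoplasma gondii, an intracellular parasite, at a multiplicity of infection of 10. The comparison asks what the infection changed in the cells' own transcripts relative to mock cells of the same time. There were 2 arrays per condition and time. The deposited intensity ran from 84.7 to 15534 over all arrays, and the array medians from 117 to 145. Between 45.6% and 49.5% of the probes were detected on an array, and 17701 probes were detected on all 12.

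The arrays differed mainly by time. Arrays of one group correlated across genes at a median r of 0.993 (6 pairs), and infected and mock arrays of one time also at a median r of 0.993 (12 pairs). Arrays of different times correlated at a median r of 0.980 (48 pairs). The leading principal components held 35.1% and 28.0% of the variance, and together they set the 3 times apart. The fourth component, with 5.37% of the variance, separated infected from mock arrays at 2 h, and the conditions overlapped on it at 24 h.

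**Figure D1:**
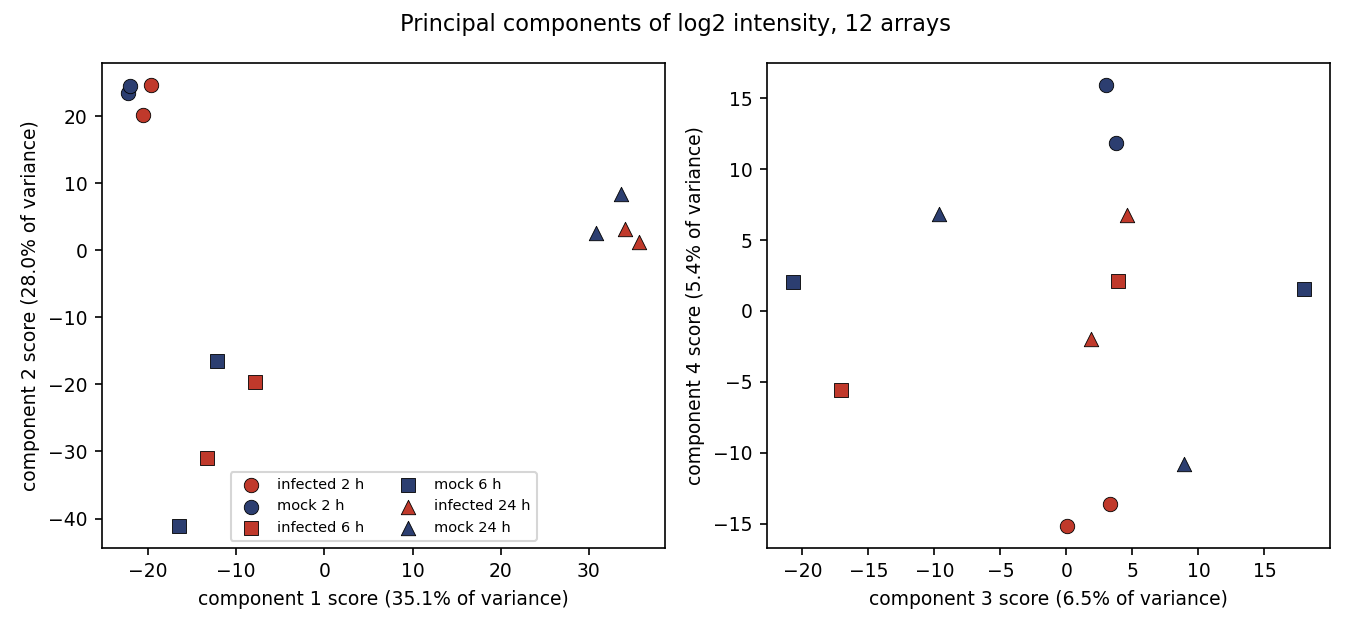
Scores of the 12 arrays on principal components 1 and 2 (left) and 3 and 4 (right) of log2 intensity, without units. Each point is an array, with colour for infected or mock and shape for time. The arrays group by time on the left. On component 4 the infected arrays at 2 h lie at -15.2 and -13.6 and the mock arrays at 11.8 and 15.9.

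At 2 h no host gene passed the test for a difference between infected and mock cells. The 3 named genes with the smallest p on the higher side were ZNF669 (0.70 ± 0.12 SE), IRGQ, which was not detected in mock cells (at least 1.43-fold), and MIR181A2HG (0.68 ± 0.12), a long non-coding transcript. On the lower side they were LRRC61 (-0.87 ± 0.12), RMRP (-1.27 ± 0.18), the RNA component of RNase MRP, and LINC00921, not detected in infected cells (at least 1.39-fold lower). In each of them both infected arrays lay on the same side of both mock arrays. In limma 0 of 21025 genes rose and 0 fell, the smallest adjusted p was 0.234, and 1598 genes had an unadjusted p under 0.05 where chance alone gives 1051. The 95% interval of the infection effect lay inside a 2-fold change for 96.6% of the genes.

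No list of immune response genes passed as a group at 2 h. Of the 41 interferon-stimulated genes and 40 NF-kappaB targets, cytokines and chemokines listed, 24 and 20 were tested. None of 24 interferon-stimulated genes passed (median -0.08, camera adjusted p = 0.892), with IRF1 at 0.38 ± 0.12 and IFITM3 at -0.42 ± 0.16. None of 20 NF-kappaB targets, cytokines and chemokines passed (median 0.07, adjusted p = 0.841), with NFKB2 at -0.69 ± 0.18 and NFKBIA, the inhibitor of NF-kappaB, at 0.38 ± 0.13. Adjusted over the list alone, 0 genes passed in these lists. Among 21 antigen presentation genes 0 passed over all genes, and adjusted over the list alone HLA-DPB1, a class II gene, fell (-0.58 ± 0.14) and 0 rose. That call is not corrected for the number of lists and times and may be chance. The smallest list p-values belonged to ribosome biogenesis genes and to ATF4 and unfolded protein response genes. Of 35 ribosome biogenesis genes 24 lay lower and 0 passed, adjusted over the list alone too (median -0.12, camera adjusted p = 0.223), with RRP9 at -0.52 ± 0.13 and GRWD1 at -0.23 ± 0.11. Of 38 ATF4 and unfolded protein response genes 26 lay lower and 0 passed, adjusted over the list alone too (median -0.05, camera adjusted p = 0.223), with PDIA4 at -0.54 ± 0.13 and CHAC1 at -0.51 ± 0.14.

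Some settings gave calls at 2 h. With median scaling in place of quantile normalization, ribosome biogenesis genes (median -0.12) and ATF4 and unfolded protein response genes (median -0.07) fell, each at a camera adjusted p of 0.00578. With a trended and robust prior 74 genes rose and 2 fell, and without background correction 34 rose and 3 fell.

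At 6 h again no gene passed. The 3 smallest p on the higher side were those of OR52D1, an olfactory receptor gene not detected in mock cells (at least 1.82-fold), SLC35G6 (0.75 ± 0.15, with its other probe at -0.14) and FOSB (0.72 ± 0.14), an immediate early transcription factor. On the lower side they were those of PPAN-P2RY11 (-0.66 ± 0.11), HGH1, not detected in infected cells (at least 1.21-fold lower), and RRP9 (-0.63 ± 0.13), a ribosome biogenesis factor. The limma test gave 0 of 21025 genes that rose and 0 that fell, a smallest adjusted p of 0.723, and 1003 genes at an unadjusted p under 0.05. For 97.6% of the genes the 95% interval lay inside a 2-fold change.

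Among 30 immediate early and MAPK response genes at 6 h, 22 lay higher and 0 passed over all genes (median 0.06, camera adjusted p = 0.399). Adjusted over the list alone FOSB rose and 0 fell; FOS stood at 0.48 ± 0.13 and KLF2 at 0.29 ± 0.13. None of 35 ribosome biogenesis genes passed (median -0.03, camera adjusted p = 0.278), and adjusted over the list alone RRP9 fell. The calls of FOSB and RRP9 are not corrected for the number of lists and times and may be chance. DNA replication and S phase genes had the smallest list p at this time, with 27 of 39 lower and 0 past the threshold (median -0.06, camera adjusted p = 0.223), and MCM2 and MCM5, subunits of the replicative helicase, stood at -0.35 ± 0.12 and -0.29 ± 0.12. Antioxidant and NRF2 genes fell on balance in fry (adjusted p = 0.0284) but not against other genes in camera (adjusted p = 0.442), with 18 of 26 lower, 0 members past the threshold, and SRXN1 at -0.28 ± 0.13. None of the interferon-stimulated genes (median -0.01, adjusted p = 0.841; IRF9 at 0.42 ± 0.12) or NF-kappaB targets (median 0.05, adjusted p = 0.841; NFKB1 at 0.19 ± 0.12) passed, adjusted over the list alone too. Without mock 6 h replicate 2, DNA replication and S phase genes fell (median -0.15, adjusted p = 0.0017) and oxidative phosphorylation genes rose (median 0.26, adjusted p = 0.00029); with array brightness as a covariate, an alternative chosen after seeing the data, the same lists passed at an adjusted p of 0.026 each. The mock array left in the former fit, replicate 1, had the lowest median of oxidative phosphorylation genes at 6 h (-0.37 from the mean of all arrays, against 0.02 and -0.14 in infected cells and 0.03 in mock replicate 2). With cyclic loess in place of quantile normalization cytosolic ribosomal protein genes fell (median -0.12, adjusted p = 0.0445).

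At 24 h no gene passed, and most of the named genes with the smallest p were not detected in infected or in mock cells. On the higher side the smallest p belonged to TBRG1 (1.09 ± 0.15), RAB34 (at least 1.17-fold) and SSTR1, a somatostatin receptor (at least 1.38-fold); RAB34 and SSTR1 were not detected in mock cells. On the lower side it belonged to CDH20, a cadherin (at least 2.00-fold lower), EML6 (at least 1.25-fold lower) and KIAA0040 (at least 1.05-fold lower), none of them detected in infected cells. In limma 0 of 21025 genes rose and 0 fell, with a smallest adjusted p of 0.169 and 1058 genes at an unadjusted p under 0.05. The 95% interval lay inside a 2-fold change for 97.0% of the genes. Without mock 24 h replicate 1, SDR16C5 alone fell (-2.38, adjusted p = 0.0096), against -1.23 at an adjusted p of 0.979 with all arrays.

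At 24 h, too, no list of immune genes passed as a group. None of the 24 interferon-stimulated genes passed (median -0.05, camera adjusted p = 0.841), with GBP1, a guanylate-binding protein detected on 1 of 2 mock arrays, at 0.41 ± 0.23 and BST2 at -0.34 ± 0.20. None of the 20 NF-kappaB targets, cytokines and chemokines passed (median -0.04, adjusted p = 0.841), with CXCL8, a neutrophil chemokine, at -0.34 ± 0.20. Adjusted over the list alone, 0 passed in both. Of 18 STAT3 and STAT6 feedback targets 0 passed over all genes (median -0.05, adjusted p = 0.952), and adjusted over the list alone SOCS3, a feedback inhibitor of cytokine signalling, rose (0.69 ± 0.15, with its other probe at 0.17) and 0 fell. This call of SOCS3 is not corrected for the number of lists and times and may be chance. The smallest list p at 24 h was that of photoreceptor and retinal neuron genes, of which 29 of 43 lay lower and 0 passed, adjusted over the list alone too (median -0.06, camera adjusted p = 0.278). GNAT1, rod transducin, stood at -0.65 ± 0.19 and PDE6B, a rod phosphodiesterase subunit, at -0.28 ± 0.15.

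Over the 3 times, 70 of 72 intervals of interferon-stimulated genes lay inside a 2-fold change. Both exceptions were OAS1, whose highest upper limit was a 2.37-fold rise. For the NF-kappaB list 58 of 60 intervals did, with NFKB2 and CXCL10 as the exceptions, and for immediate early genes 89 of 90, with FOSB as the exception. These intervals speak for detected genes: 14 of the 24 interferon-stimulated genes and 10 of the 20 NF-kappaB genes were detected on all arrays.

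**Figure D2:**
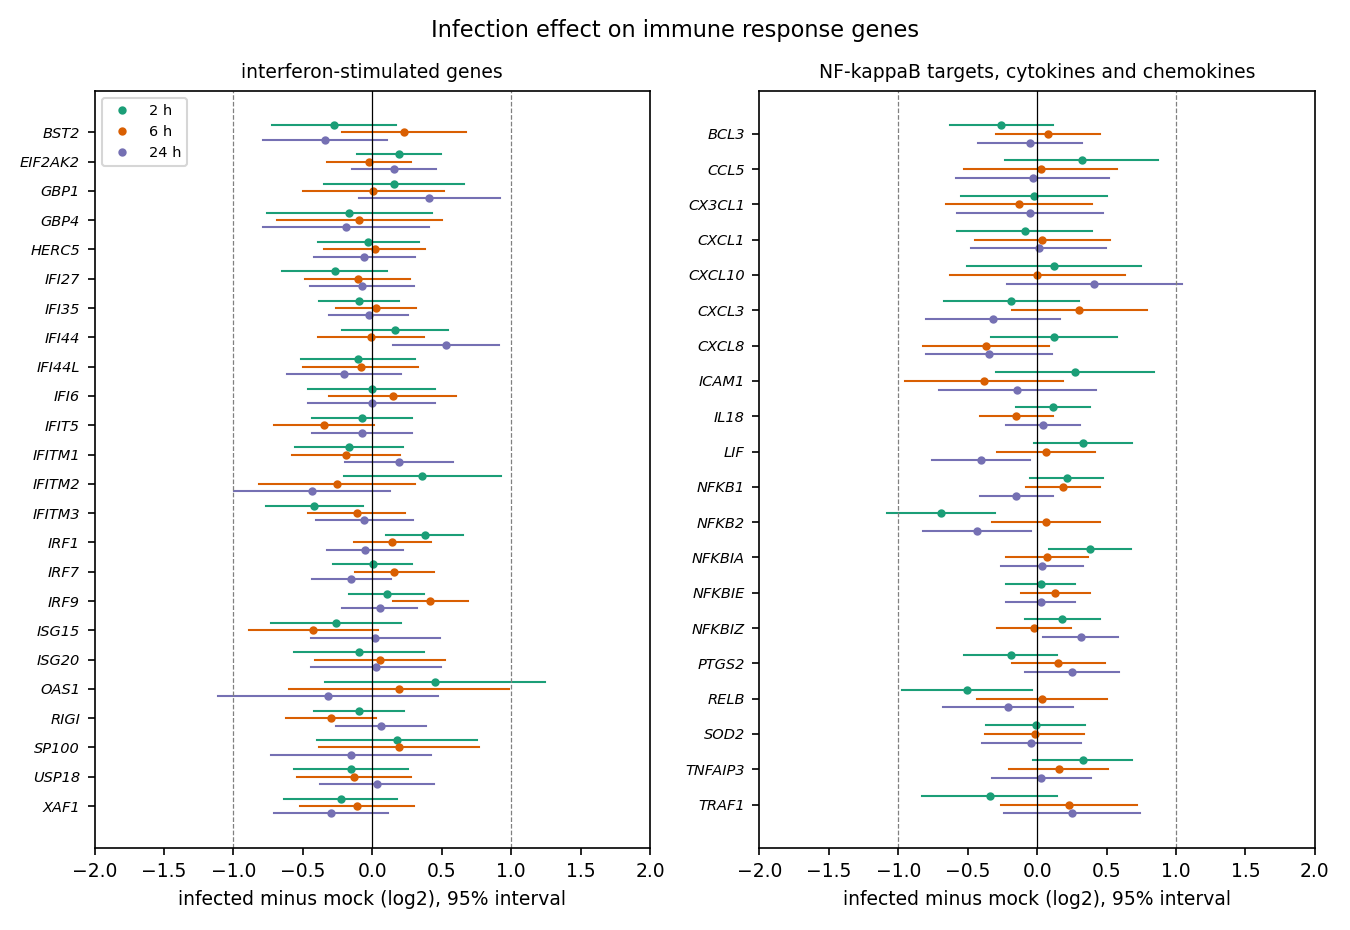
Infected minus mock difference (log2, horizontal axis) of each tested interferon-stimulated gene (left) and NF-kappaB target, cytokine or chemokine (right). Points are limma estimates and bars their 95% intervals, from 2 arrays per group, with a colour for each time; dashed lines mark a 2-fold change. No gene passed the adjusted threshold, and 70 of 72 and 58 of 60 intervals lie inside the dashed lines.

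No list of markers of other cell types passed the test for a difference between infected and mock cells. None of 21 fibroblast markers, 7 Muller glia and astrocyte markers, 6 retinal pigment epithelium markers, 8 microglia, macrophage and lymphocyte markers or 5 vascular endothelium markers passed at any time. Their smallest camera adjusted p over the 3 times were 0.399, 0.730, 0.479, 0.740 and 0.730. Adjusted over the list alone, CD68, a lysosomal protein of macrophages, rose (0.78 ± 0.18, with its other probe at 0.08) and C1QA, a complement subunit, fell (-0.67 ± 0.20) at 2 h, and at 24 h PECAM1, an endothelial adhesion molecule not detected in mock cells, rose (at least 1.36-fold) and ESAM fell (-0.38 ± 0.13). These single-gene calls are not corrected for the number of lists and times and may be chance. None of 13 RNA content genes passed (smallest camera adjusted p = 0.765). Over all 27 lists and 3 times camera called 0 of 81 tests at the preset correlation (smallest adjusted p = 0.223) and 0 with an estimated correlation. The tests of fry called 1, the antioxidant list at 6 h, for movement on balance and 0 for change in either direction (smallest adjusted p = 0.114).

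Averaged over the 3 times, with 6 infected and 6 mock arrays, 0 genes rose and 0 fell in limma, with a smallest adjusted p of 0.535 and 1319 genes at an unadjusted p under 0.05. Ribosome biogenesis genes and photoreceptor and retinal neuron genes came closest to a shift. Of the former 24 of 35 lay lower (median -0.04, camera adjusted p = 0.0618), and fry found change in either direction (adjusted p = 0.0043); adjusted over the list alone 1 member fell. Of the latter 32 of 43 lay lower (median -0.05, adjusted p = 0.0618). Antioxidant and NRF2 genes fell on balance in fry (median -0.03, adjusted p = 0.00699) and not in camera (adjusted p = 0.338). The infection effect differed between times for 0 genes in limma. Unadjusted p under 0.05 were found for 1244 genes between 2 and 6 h, 909 between 6 and 24 h and 1378 between 2 and 24 h. Across genes, which are not independent replicates, the effects at different times correlated at r of 0.0351 (2 and 6 h), -0.0213 (2 and 24 h) and 0.0421 (6 and 24 h).

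Many genes changed over time in mock cells. Between 2 and 6 h the list of immediate early and MAPK response genes fell, and that of heat shock genes rose at the preset correlation only (adjusted p = 0.0519 with an estimated correlation). FOSB (-3.82 ± 0.14) and FOS (-2.67 ± 0.13) fell, and RMRP, not detected at 6 h, fell at least 4.22-fold. HSPA6 rose by 2.26 ± 0.16 (0.97 in its other probe) and HSPA1B by 1.69 ± 0.19, both inducible HSP70 chaperones, and NQO1, a quinone reductase under NRF2 control, by 1.90 ± 0.12. HSPA1B and HSPA1A are near-identical copies, and their probes may not tell them apart. In limma 1305 genes rose and 1505 fell, 13.4% of those tested. The count was 637 without mock 2 h replicate 1, 596 without mock 2 h replicate 2, 1007 without mock 6 h replicate 1 and 1540 with array weights.

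Of 30 immediate early and MAPK response genes, 17 fell and 0 rose between 2 and 6 h in mock cells (19 and 0 adjusted over the list alone; median -0.49, camera adjusted p = 8.5e-12, 0.0172 with an estimated correlation), among them the transcription factor EGR1 (-2.35 ± 0.14) and SPRY4, an inhibitor of MAPK signalling (-2.12 ± 0.19). Of 22 heat shock genes 8 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.30, adjusted p = 0.00047, 0.0519 with an estimated correlation), with the co-chaperones DNAJB4 (1.53 ± 0.17) and CHORDC1 (1.18 ± 0.15). Of 24 cholesterol synthesis and uptake genes 9 rose, 2 fell and 13 did not pass (9 and 3 adjusted over the list alone; median 0.29, adjusted p = 0.0084, 0.139 with an estimated correlation). HMGCS1 (1.04 ± 0.14) and IDI1 (0.92 ± 0.15) encode enzymes of the mevalonate pathway and INSIG1 (0.93 ± 0.14) a sterol sensor, while ABCG1, a sterol exporter, fell (-1.03 ± 0.11; 1 of its 4 other probes had the opposite sign). Of 35 glycolysis and hypoxia genes 10 fell and 2 rose (13 and 3 adjusted over the list alone; median -0.21, adjusted p = 0.00093, 0.0519 with an estimated correlation), with the collagen hydroxylase P4HA1 (-1.12 ± 0.12), DDIT4 (-0.92 ± 0.15) and the mitophagy receptor BNIP3 (-0.66 ± 0.11). Of 21 antigen presentation genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.28, adjusted p = 0.0017, 0.139 with an estimated correlation), with HLA-DMB (-1.41 ± 0.19) and the peptide transporter subunits TAP1 (-0.58 ± 0.12) and TAP2 (-0.68 ± 0.14, with its other probe at 0.04). Of 26 antioxidant and NRF2 genes 6 rose and 2 fell without a shift of the list (7 and 2 adjusted over the list alone; median 0.02, adjusted p = 0.213), with GCLM (1.07 ± 0.14) and GCLC (0.84 ± 0.16), the subunits of the enzyme that starts glutathione synthesis.

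**Figure D3:**
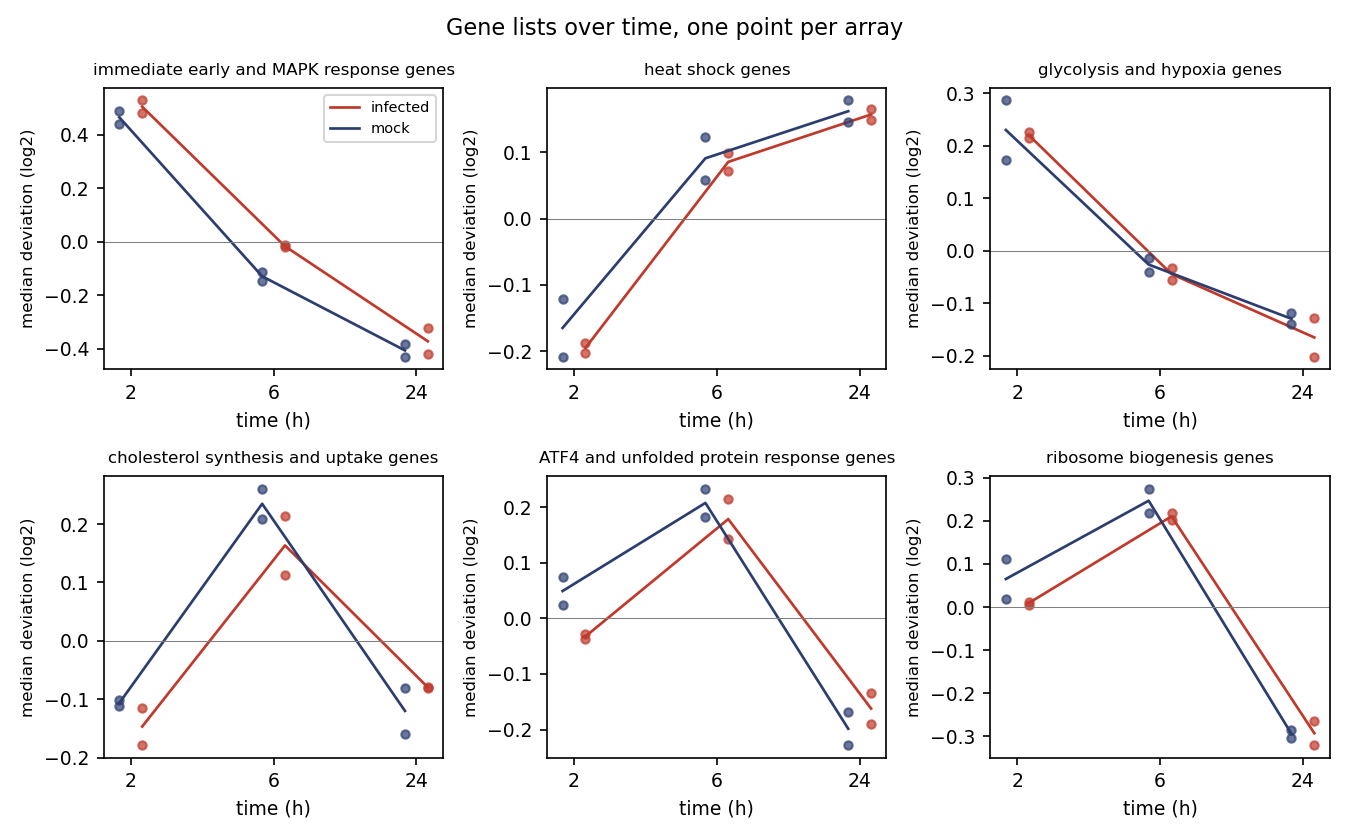
Median deviation of 6 gene lists from each gene's mean over all arrays (log2, vertical axis) at 2, 6 and 24 h (horizontal axis, not to scale). Each point is an array and lines join the group means of infected and mock cells. Immediate early genes fall over both steps, and ribosome biogenesis, ATF4 and cholesterol genes stand highest at 6 h in both conditions.

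Between 6 and 24 h ribosome biogenesis genes and the ATF4 program fell in mock cells, together with ID1 and ID3, inhibitors of basic helix-loop-helix transcription factors. The values were -3.68 ± 0.12 for ID1, -2.62 ± 0.13 for ID3 and -2.91 ± 0.22 for SAMD11, a transcript of photoreceptors whose other probe gave -1.16. The largest rises were those of STMN2, a microtubule regulator of growing neurites (2.39 ± 0.18), and of the small nuclear RNAs SCARNA11 (2.08 ± 0.20) and RNU4-2 (1.95 ± 0.30). Small RNA genes as a class did not rise. The median deviation of all 189 tested from the mean of all arrays was -0.08 and 0.01 in mock cells at 6 h. At 24 h it was -0.06 and -0.09. In limma 1727 genes rose and 1792 fell. The count of 3519 was 1814 without mock 6 h replicate 1, 1485 without mock 24 h replicate 1, 1969 without mock 24 h replicate 2, 2215 in a fit of the arrays of these times alone, 1749 with array weights and 2303 with array brightness as a covariate. With median scaling the median of all genes moved to 0.13, and 1887 genes rose and 1295 fell.

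Of 35 ribosome biogenesis genes 22 fell and 1 rose between 6 and 24 h (26 and 1 adjusted over the list alone; median -0.57, camera adjusted p = 6.3e-12, 0.0208 with an estimated correlation), among them RRP9 (-0.93 ± 0.13), RRP12 (-0.92 ± 0.13), PNO1 (-0.79 ± 0.11) and the nucleolar helicase DDX21 (-0.99 ± 0.15). Of 38 ATF4 and unfolded protein response genes 17 fell and 1 rose (20 and 2 adjusted over the list alone; median -0.46, adjusted p = 1.5e-06, 0.0208 with an estimated correlation), with the pseudokinase TRIB3 (-1.30 ± 0.11), asparagine synthetase ASNS (-1.45 ± 0.17) and STC2 (-1.30 ± 0.12). Immediate early genes fell further, with 12 lower and 2 higher of 30 (13 and 2 adjusted over the list alone; median -0.33, adjusted p = 0.0003, 0.0519 with an estimated correlation), with FOS at -2.38 ± 0.13 and EGR1 at -2.07 ± 0.14. Of 24 cholesterol genes 10 fell and 2 rose (10 and 3 adjusted over the list alone; median -0.26, adjusted p = 0.0327, 0.211 with an estimated correlation), with SC5D (-0.92 ± 0.15), NSDHL (-0.65 ± 0.10) and a rise of ABCG1 (1.55 ± 0.11). This list did not pass without mock 6 h replicate 2 (adjusted p = 0.0514) or mock 24 h replicate 1 (adjusted p = 0.0607). Of 26 antioxidant genes 5 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.21, adjusted p = 0.0082, 0.0842 with an estimated correlation), with NQO1 at -1.09 ± 0.12 and GCLM at -0.99 ± 0.14.

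The list of DNA replication and S phase genes and that of RNA content genes also fell between 6 and 24 h, but these calls were less firm. Of 39 S phase genes 8 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.15, camera adjusted p = 0.0078, 0.494 with an estimated correlation), with RRM2, a ribonucleotide reductase subunit, at -1.28 ± 0.21 and MCM2 at -0.56 ± 0.12. With median scaling the median turned to 0.01 and the call was lost (adjusted p = 0.105), as it was without mock 6 h replicate 1 (adjusted p = 0.0998). Of 13 RNA content genes 3 fell and 0 rose, adjusted over the list alone too (median -0.29, adjusted p = 0.0082, 0.407 with an estimated correlation). These were PPIA (-0.93 ± 0.15), ACTB (-0.61 ± 0.13) and HPRT1 (-0.38 ± 0.11). Their list did not pass with median scaling (adjusted p = 0.107), without mock 6 h replicate 1 (0.0888) or without mock 24 h replicate 1 (0.0522). These household genes fell over the same interval as the ribosome biogenesis, ATF4, cholesterol and antioxidant lists.

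Over the whole span from 2 to 24 h in mock cells, the 3 largest falls among named genes were those of immediate early and MAPK response genes, and HSPA1B and HSPA1A were among the 3 largest rises. FOS (-5.04 ± 0.13), FOSB (-5.04 ± 0.14) and EGR1 (-4.42 ± 0.14) fell, and SPRY4, not detected at 24 h, was at least 22.5-fold lower; its 2 other probes gave smaller falls. HSPA1B rose by 2.71 ± 0.19, HSPA1A, not detected at 2 h, at least 4.13-fold, and the sialyltransferase ST6GALNAC5 by 2.41 ± 0.14. In limma 1792 genes rose and 1832 fell. The count of 3624 was 1458 without mock 2 h replicate 1, 1456 without mock 2 h replicate 2, 1909 without mock 24 h replicate 1 and 1919 without mock 24 h replicate 2. With median scaling 2149 rose and 1291 fell, around a median of all genes of 0.12.

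**Figure D4:**
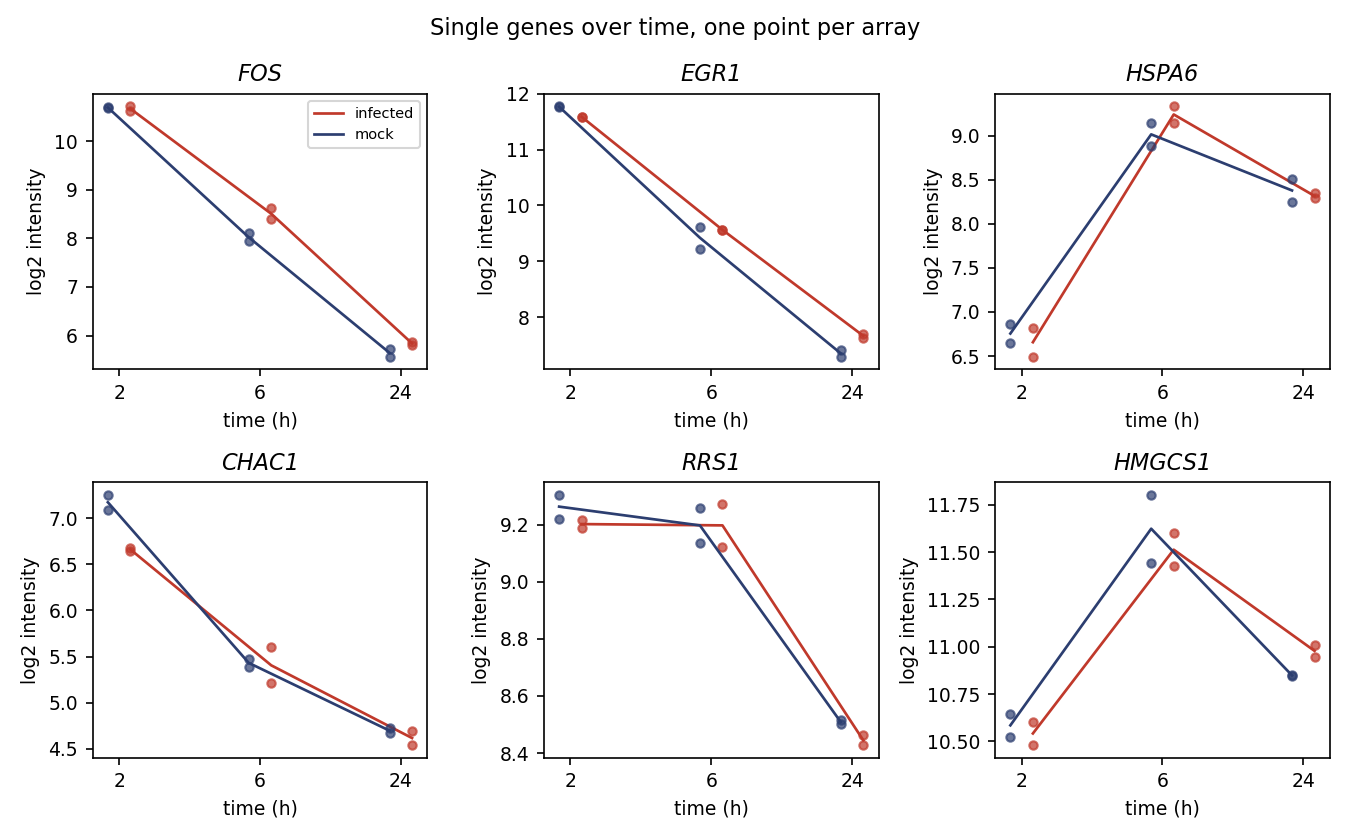
Log2 intensity (vertical axis) of 6 genes at 2, 6 and 24 h (horizontal axis, not to scale). Each point is an array and lines join the group means of infected and mock cells. In mock cells FOS goes from a mean of 10.69 at 2 h to 5.65 at 24 h, and EGR1 from 11.77 to 7.35.

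Of 30 immediate early genes 22 fell and 2 rose over this span (24 and 2 adjusted over the list alone; median -0.80, camera adjusted p = 4.6e-15, 0.0161 with an estimated correlation). Of 35 glycolysis and hypoxia genes 16 fell and 5 rose (20 and 5 adjusted over the list alone; median -0.40, adjusted p = 5.2e-05, 0.0483 with an estimated correlation), with the glucose transporter SLC2A1 (-1.38 ± 0.13), ALDOC (-1.42 ± 0.13), DDIT4 (-1.86 ± 0.15) and PFKL (-1.37 ± 0.12, with its other probe at -0.15). Of 35 ribosome biogenesis genes 18 fell and 0 rose (20 and 0 adjusted over the list alone; median -0.37, adjusted p = 2.6e-07, 0.0516 with an estimated correlation), with PPAN (-1.28 ± 0.14) and RRS1 (-0.75 ± 0.11). Of 38 ATF4 genes 10 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.22, adjusted p = 0.0017, 0.0519 with an estimated correlation), with CHAC1, a glutathione-degrading enzyme (at least 4.09-fold lower), and DDIT3 (-1.06 ± 0.13). Of 22 heat shock genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.35, adjusted p = 0.00028, 0.0519 with an estimated correlation), HSPA6 by 1.62 ± 0.16; with a stricter probe filter this list did not pass (median 0.07, adjusted p = 0.0930). Of 21 antigen presentation genes 7 fell and 0 rose (8 and 0 adjusted over the list alone; median -0.27, adjusted p = 0.0021, 0.140 with an estimated correlation), with HLA-DPA1 at -0.94 ± 0.12. Of 8 microglia, macrophage and lymphocyte markers 3 fell and 1 rose, adjusted over the list alone too (median -0.39, adjusted p = 0.0923), with CD2, a lymphocyte adhesion molecule, at -1.20 ± 0.19, AIF1 at -0.53 ± 0.14 and CD68 at 0.80 ± 0.18. This rise of CD68 and its difference with infection at 2 h (0.78) are measured from the same mock arrays at 2 h. CD68 is also among the genes called at 2 h under the trended and robust prior. Of 13 RNA content genes 2 fell and 0 rose, adjusted over the list alone too, without a call for the list (median -0.19, adjusted p = 0.0964). Cholesterol genes did not differ as a list between 2 and 24 h (2 rose and 1 fell of 24, adjusted over the list alone too; median 0.05, adjusted p = 0.536).

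Retinal genes went both ways in mock cells between 2 and 24 h. Of 43 photoreceptor and retinal neuron genes 7 rose, 7 fell and 29 did not pass (10 and 10 adjusted over the list alone; median -0.02, camera adjusted p = 0.553). The cone opsins OPN1MW and OPN1LW, near-identical copies whose probes may not be told apart, fell (-2.67 ± 0.12 and -2.76 ± 0.15). NR2E3, a photoreceptor transcription factor not detected at 24 h, fell at least 1.26-fold. GAP43, a growth cone protein, rose by 1.71 ± 0.18.

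Many of the same changes were seen in infected cells, on arrays that share none with the mock comparison. Both comparisons come from the same fit, with a shared estimate of the spread for each gene, and from arrays normalized together. Their lists are therefore not independent, and the numbers given for independent lists are only a reference. Between 2 and 6 h 1178 genes rose and 1063 fell in infected cells, between 6 and 24 h 1346 and 1543, and between 2 and 24 h 1838 and 1855. Between 2 and 6 h, 646 genes rose and 719 fell in both conditions, where independent lists would share 73.1 and 76.1. Between 6 and 24 h, 913 rose and 1081 fell in both, against 111 and 132 for independent lists. Between 2 and 24 h, 1027 rose and 1191 fell in both, against 157 and 162. Genes called in opposite directions numbered 2, 5 and 5. Of the 18 gene list calls in mock cells 17 were also made in infected cells in the same direction, and the exception was the fall of cholesterol genes between 6 and 24 h. Another 5 list calls were made in infected cells alone. Between 2 and 6 h ATF4 and unfolded protein response genes rose (8 rose and 3 fell of 38, 15 and 4 adjusted over the list alone; median 0.20, adjusted p = 0.0089, 0.0924 with an estimated correlation), as did G2 and mitosis genes (1 and 0 of 37, 0 and 0 adjusted over the list alone; median 0.17, adjusted p = 0.0131, 0.450 with an estimated correlation) and ribosome biogenesis genes (6 and 1 of 35, 11 and 3 adjusted over the list alone; median 0.13, adjusted p = 0.0389, 0.296 with an estimated correlation), while tight junction, adhesion and extracellular matrix genes fell (0 and 6 of 25, 0 and 9 adjusted over the list alone; median -0.15, adjusted p = 0.0407, 0.162 with an estimated correlation). Between 2 and 24 h RNA content genes fell (0 and 2 of 13, 0 and 3 adjusted over the list alone; median -0.14, adjusted p = 0.0389, 0.452 with an estimated correlation). Camera called 0 of 81 list tests for a difference of the infection effect between times (smallest adjusted p = 0.570). With an estimated correlation 5 of the 18 calls in mock cells and 7 of the 22 in infected cells passed.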

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

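No named gene or list past the threshold passed in the opposite direction under an alternative; the median of DNA replication and S phase genes between 6 and 24 h in mock cells went from -0.15 to 0.01 with median scaling, without passing. For infected against mock cells, the counts of 0 held in each alternative for 6 h, for the differences between times and for the mean over times. At 2 h a trended and robust prior gave 74 genes that rose and 2 that fell, and no background correction gave 34 and 3; 35 of these 37 were also called under the trended prior. A shared factor of the genes called under the trended prior is a candidate cause (mean correlation 0.496, which measures neither its size nor its nature). The cause of the dependence on the background was not tested. Of the list tests with infection, 2 passed with median scaling, 1 with cyclic loess and 2 with array brightness as a covariate (chosen after seeing the data); the cause was not tested.

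Leaving out each array in turn assumes that the lone array of its group varies like the other groups. It gave 0 to 1 gene that fell at 24 h (SDR16C5), 0 for the other infection counts, and 0 to 2 list calls with infection. In mock cells the counts ran from 596 (without mock 2 h replicate 2) to 4169 (without mock 6 h replicate 2) for 2 to 6 h, from 1485 (without mock 24 h replicate 1) to 4486 (without mock 6 h replicate 2) for 6 to 24 h, and from 1456 (without mock 2 h replicate 2) to 1919 (without mock 24 h replicate 2) for 2 to 24 h; the list calls ran from 16 to 21 around 18. Fewer arrays in a contrast widen its errors, which lowers counts by construction. The rise without mock 6 h replicate 2 was not traced by a test. The array then left alone in its group, replicate 1, stood at -41.1 on component 2, against -16.5 for replicate 2. The gap between these arrays also drops out of the error estimate. The counts that use mock cells at 6 h thus depend on which array is kept.

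Against 2810, 3519 and 3624 genes that changed in mock cells between 2 and 6 h, 6 and 24 h, and 2 and 24 h, a 2-fold minimum left 330, 525 and 560, and an adjusted p under 0.01 left 727, 1250 and 1458, both stricter by construction. Array weights gave 1540 and 1749 for the steps to 6 h and to 24 h. For 6 to 24 h, a fit of the arrays of these times alone, with fewer samples, gave 2215, and brightness as a covariate (chosen after seeing the data) 2303. Of 4008 alternative values of named genes past the threshold 3553 stayed past it and 455 did not; of 6468 values of named genes short of it, 145 passed and 38 changed sign without passing. Of 324 values of the list calls in mock cells 316 held.

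With the replicate number as a block, 2294, 2972 and 3167 genes changed in mock cells in these intervals, 0 with infection, and 18 list calls were made in mock cells. The numbers do not pair the arrays: deviations from group means of same-numbered infected and mock arrays correlated at 0.00435 at 2 h, -0.326 at 6 h and 0.0110 at 24 h. Crossing the numbers at 6 h (chosen after seeing the data) gave 0 genes. Slide as a block was not run, since the files give no slide. Signal over background limits dim genes: without the probe filter 37164 genes were tested, with the stricter one 12793.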

Other observations

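Several gene groups not yet described changed members in mock cells without a shift of the list. Of 30 p53 target and apoptosis genes 3 rose and 6 fell between 6 and 24 h (4 and 9 adjusted over the list alone; camera adjusted p = 0.225), with the stress cytokine GDF15 at -1.14 ± 0.13 and the cell cycle inhibitor CDKN1A at -0.66 ± 0.13. Of 15 polyamine and arginine metabolism genes 6 fell and 1 rose over the same step (6 and 1 adjusted over the list alone; adjusted p = 0.0932), with the arginine transporter SLC7A1 at -0.89 ± 0.11 and ornithine decarboxylase ODC1 at -0.60 ± 0.14, and OAZ2, an ornithine decarboxylase antizyme, at 1.12 ± 0.24. Of 27 autophagy and lysosome genes 6 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.779), with the kinase ULK1 at 0.87 ± 0.11 and GABARAPL1 at 0.89 ± 0.14. Of 25 tight junction, adhesion and extracellular matrix genes 5 fell and 0 rose between 2 and 6 h (6 and 0 adjusted over the list alone; adjusted p = 0.163), with LAMA5, a laminin chain, at -0.94 ± 0.11 and the protease MMP9 at -0.99 ± 0.18; the difference between infected and mock cells in this step did not pass (adjusted p = 0.923).

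Of the tests that follow, those of exchanged arrays, of small RNA recovery, of array brightness, of splits that call genes and of the 6 h pairs against the changes over time were chosen after the result was seen.

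No gene passed for infection at 2, 6 or 24 h. Many missed responses of 2-fold or more are argued against for detected genes. At the time with the lowest share 96.6% of the genes tested had a 95% interval inside a 2-fold change. These intervals say little about dim genes, and 17701 of the 26035 kept probes were detected on all 12 arrays. In the simulation 72.0% of the genes changed 2-fold at 24 h were recovered, so single responses of that size may be missed. An exchange of an infected and a mock array at 2 or 24 h that hid genes able to pass is argued against, since the other splits of those 4 arrays also called 0 genes in limma, with at most 653 genes at an unadjusted p under 0.05 against 1598 at 2 h and 1067 against 1058 at 24 h; an exchange that hid smaller differences is not excluded at 24 h. At 6 h an exchange cannot be told apart from other causes: setting infected replicate 1 and mock replicate 2 against the other arrays called 114 genes, but that difference correlated across genes at only 0.0386 and -0.0819 with the infection effects at 2 and 24 h, where no gene passed. For the mean over the 3 times, 34 of 100 splits drawn of 108 possible gave at least the real 1319 genes at an unadjusted p under 0.05 (median other 1076, highest other 2842). Chance cannot be excluded for that count. Some of these splits contain the crossed 6 h grouping with its 3514 genes at an unadjusted p under 0.05, and they were not set apart. The share of 34 may thus reflect that structure of the 6 h samples. The count past the threshold decides nothing, since any of the 100 splits gives at least the real 0 (highest other 23). A response smaller than these intervals, or one in a part of the cells, stays open and was not tested, since the arrays hold no named parasite probes that would measure infection.

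The 6 h arrays fall into pairs that cross infection and mock. In infected replicate 1 and mock replicate 2 together 107 genes were higher and 7 lower than in the other arrays, and 3514 had an unadjusted p under 0.05 against 1003 for infection (1070 passed under the trended and robust prior, against 0 for infection), which points to a structure of these samples. Small RNA genes such as SNORA12 (1.66) and RNU1-1 (1.07) made up 23.2% of the 69 named genes called, against 1.39% of all named genes (Fisher's exact test, two-sided, p = 9.9e-16). The called genes come from 1 split of 4 arrays and are not independent, so this p-value overstates the evidence. Over all 189 small RNA genes the median deviation from the mean of all arrays was 0.010 in infected replicate 1 and 0.012 in mock replicate 2. In the other 6 h arrays it was -0.097 and -0.081. The share of 23.2% lies just under the 25% set for uneven recovery of small RNA, so that cause may hold for part of the genes and cannot be told apart from others. The calls also include small mitochondrial proteins such as ATP5ME (0.97) and ROMO1 (0.92). With array brightness as a covariate the median absolute difference of the 114 genes called did not shrink (0.91 against 0.90 without it). However, 0 of 114 stayed past the threshold, while the median SE rose from 0.14 to 0.19. The rule written for brightness took calls that stay as the sign against it, and lost calls with a shrunken difference as the sign for it. Neither outcome was met, so brightness cannot be told apart from other causes. Across genes the difference correlated at 0.321 with the change of mock cells from 6 to 24 h and at -0.342 with the mean change of both conditions from 2 to 6 h, but both comparisons share the 6 h arrays with it, so that 1 deviant array would give the same signs, and they decide nothing; a difference between the pairs in their course over time stays open.

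At 2 h, 76 genes passed under the trended and robust prior, of which 46 are named and 30 are unnamed probes, against 0 in the other splits of the 2 h arrays, with a median of the mean log2 intensity of 10.09 against 6.90 for all genes. A shared factor of these probes that also varies without regard to infection is a candidate explanation: at 6 and 24 h their deviations from group means correlated at a mean of 0.496, above the highest of 1000 random lists matched on level (0.0788). Each gene's deviations were first scaled to equal length, so this correlation does not measure their size. It rests on 4 groups, which include those of 6 h with their crossed pairs. Genes regulated together would also exceed random lists, so the correlation does not tell what the factor is. For the 74 that were higher, the median deviation at 6 h was 0.12 in infected replicate 1 and 0.07 in mock replicate 2. At 24 h it was 0.04 in replicate 2 of both conditions. Whether the factor is large enough for the difference at 2 h was not tested. Such a factor makes the genes move together and so may yield many calls from few independent differences. In these 74 genes the mock arrays at 2 h (-0.50 and -0.43 from the mean of all arrays) stand apart. The infected arrays at 2 h (0.17 and 0.19) lie near those of 24 h (0.15 to 0.26). The 6 h arrays (0.10 and -0.19 in infected, -0.13 and 0.02 in mock cells) lie between the infected and mock arrays of 2 h. The genes were chosen for their difference at 2 h, so the levels at 2 h decide nothing. An effect of infection at 2 h stays open as untested.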
